A study of Mus musculus with 2 samples.

How the data were processed

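H3K27ac ChIP-seq was done by the authors on liver pooled from male and female embryos of mouse strain B6NCrl at embryonic day 13.5, in 2 biological replicates of 1 group, with library fragments of 300 to 500 bp. The 4 deposited peak lists were on mm10 in narrowPeak format: 1 called on each replicate, 1 called on the reads of both replicates pooled, and 1 of replicated peaks derived from the other 3. Each deposited peak has an enrichment, a signal value that the authors' peak caller gives relative to its background model. The authors also give a -log10 p and a -log10 q per peak. The caller, the aligner, their versions and the rule for keeping a replicated peak are not given in the sources used here. The enrichment was used only to rank or describe peaks within a list, and no list was rescaled. The files hold no read counts, so the depth of each library and the precision it would give are unknown, and no interval that needs depth is given. Genes are not replicates, and each test across genes or peaks describes these libraries.

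Peak ends were checked against the chromosome lengths of GRCm38, and genes, exons and TSSs were taken from GENCODE release M21 on that build. The 21911 protein-coding genes with distinct symbols on 21 chromosomes were used. Overlaps were computed with bedtools 2.31.1, and everything else in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Peaks of the replicates counted as shared when the overlap was at least 50% of either peak, and chance overlap was taken from 100 circular shifts within each chromosome. The Spearman rho of the enrichment was taken across shared peaks, with no p.

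A gene had a TSS peak when a replicated peak lay within 1 kb of any of its annotated TSSs, and its covered bases were counted within 5 kb of its most 5' TSS. Location was given in the order TSS window of 1 kb, exon, intron, intergenic. The promoter CpG ratio, observed over expected, was taken within 500 bp of the TSS and split into 5 quintiles of genes.

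The 17 gene lists were fixed before the data were examined, together with the comparisons, the tests, the words for transcription factors, the named-gene rule and most alternatives. The lists were erythroid, heme biosynthesis and iron, fetal hepatocyte and hepatoblast, mature hepatocyte function, cholangiocyte, haematopoietic stem and progenitor, megakaryocyte, myeloid and macrophage, lymphoid, endothelial, stellate and mesenchymal, neural, cardiac and skeletal muscle, limb and cartilage, other endoderm and kidney, cell cycle and housekeeping. Of 341 entries 340 were matched to the annotation, and Ahsp was not. The number of members with a TSS peak and the median covered bases of each list were compared with 10000 random lists of the same size from protein-coding genes, which is a permutation of the list labels over genes, two-sided. The 8 list pairs were compared by a permutation test of the difference in mean covered bases with 100000 resamples, two-sided. Adjusted p is by Benjamini and Hochberg over the lists, pairs or words of a family, with a threshold of 0.05.

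Replicated peaks within 12.5 kb were stitched and ranked by covered bases, and regions beyond the point where the ranked curve, scaled to 1 by 1, has slope 1 were called large. Members of each list that overlap a large region were tested by Fisher's exact test, one-sided, against other protein-coding genes. The 16 words were counted on both strands in peaks more than 2.5 kb from a TSS and in windows of the same length 10 kb to each side that overlap no pooled-read peak. Each ratio of matches per kb, with 0.5 added to both counts, was set against 100 letter-shuffled versions of the word, two-sided. In the text are named the nearest genes of the 12 stitched regions with most covered bases, in each list the 3 members with most covered bases and the first 2 by symbol without a TSS peak, and the nearest genes of the 10 peaks of highest enrichment. Genes named outside this rule were chosen after their values were seen.

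Repeated sequence was measured as the percentage of 50-base words, taken every 25 bases within 5 kb of a TSS, that occur again in the genome on either strand. The steps were tested on simulated data: lists of 20 genes with no effect had p under 0.05 in 3.5% of cases, and lists with a TSS peak at 90% or 10% of members in 99% of cases. A list with 0 covered bases at all members was never called by the median test. With 2 planted words, 0 words were called with 100 shuffled versions and 3 with 1000 sharing no word with the consensus, which included both planted ones.

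Alternatives were a -log10 q of at least 2, overlap by 1 base or by 50% of both peaks, equal numbers of top peaks, other TSS windows, CpG-matched random lists, the pooled-read list, each replicate's list alone, other stitching distances and ranks, and other flanks or peaks for the words. Chosen after seeing the data were the 20000 peaks of highest -log10 p, strict against all peaks, genes with under 10% of words repeated, the TSS with most covered bases, members with no other TSS in the window, and 1000 shuffled versions sharing no word with the consensus. Peaks on sequences outside the assembled chromosomes were left out of every comparison with genes, because the gene set is limited to the chromosomes.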

Results

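Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by ChIP-seq in liver from mouse embryos of strain B6NCrl at embryonic day 13.5. The tissue was pooled from male and female embryos, and the labels give 2 biological replicates in 1 group. No second tissue, stage or treatment was part of the series, so each comparison below sets peak lists, gene lists or genome regions against each other within this liver. Values came from 4 peak lists on the mm10 build (GRCm38), 1 per replicate, 1 called by the authors on pooled reads, and 1 of replicated peaks. The depth of each library is unknown, since the peak lists hold no read counts. At this stage the liver is a site of blood formation and holds hepatoblasts, the precursors of hepatocytes, and the gene lists fixed for the comparisons cover both.

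The first comparison asked whether the replicates placed H3K27ac in the same regions. The strongest peaks were shared almost completely, and the weak ones mostly were not. In the highest decile of the authors' -log10 p, 99.97% of replicate 1 peaks and 99.96% of replicate 2 peaks were overlapped by a peak of the other replicate, by at least 50% of either peak. In the lowest decile the shares were 20.8% and 17.8%. Replicate 1 had 109241 peaks and replicate 2 had 107046, a mean of 108144 ± 1552 (SD, n = 2), and they covered 57.2 ± 0.567 Mb (SD, n = 2), or 2.10% of the genome. Over all peaks, 50.6% of replicate 1 and 50.5% of replicate 2 peaks were overlapped, and the Jaccard index of the covered bases was 51.2%. After 100 circular shifts of 1 list along each chromosome, the overlapped share of replicate 1 was 3.19% ± 0.234 (SD over shifts), with a highest value of 4.34%. Across 55231 shared peaks, which are not independent replicates, the authors' enrichment had a Spearman rho of 0.667 between replicates. The overlapped share depended on its definition: it was 32.7% when 50% of both peaks had to overlap and 83.5% among the 20000 peaks of highest -log10 p in each list, the latter chosen after seeing the data.

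**Figure D1:**
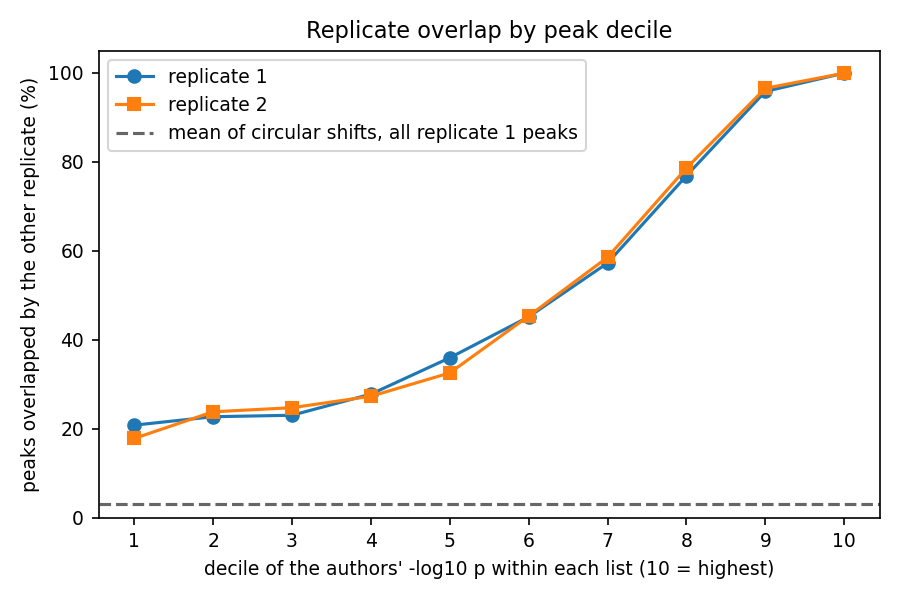
Percentage of each replicate's peaks overlapped by the other replicate (y axis) against the decile of the authors' -log10 p within the list (x axis, 10 the highest), with circles for replicate 1 and squares for replicate 2. Both lines rise from 20.8% and 17.8% to 99.97% and 99.96%, above the dashed mean of circular shifts, which was 3.19% for all replicate 1 peaks.

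The next comparison asked what the replicated list holds. All 60368 replicated peaks had the coordinates, enrichment and -log10 p of a pooled-read peak, so 49.7% of the 121381 pooled-read peaks were kept. Each of the 49266 pooled-read peaks overlapped by both replicate lists was kept, and a further 11102 replicated peaks were not overlapped by both at 50% of either peak. Kept peaks had a median width of 579 bp and a median enrichment of 4.26, against 220 bp and 2.71 for the 61013 others. The replicated list covered 59.6 Mb and is the list used from here on where no other is named, and values from the replicates' own lists are given for only some of the results.

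H3K27ac was concentrated at gene starts. Replicated peaks that reached within 1 kb of an annotated transcription start site (TSS) made up 35.4% of peaks. The full length of these peaks came to 28.7 Mb of the 59.6 Mb covered. The windows of 1 kb on each side of a TSS held 33.9% of the covered bases, 5.76 times their share of the genome. Exons outside these windows held 8.50% of peaks, introns 37.8% and intergenic sequence 18.4%, and the intergenic share of covered bases was 0.352 times its genome share. More than 2.5 kb from any TSS lay 31688 peaks, or 52.5%. The share at a TSS was lower in the longer lists, 26.0% in the pooled-read list and 27.6% and 27.8% in the lists of replicates 1 and 2. Of 21911 protein-coding genes, 11237 (51.3%) had a replicated peak within 1 kb of a TSS. The replicate lists gave 11853 and 11836 genes, with 11159 in both. The share rose with the CpG content of the promoter, from 11.5% of genes in the lowest CpG quintile to 86.5% in the highest.

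The peaks of highest enrichment in the list lay at genes of several kinds. By the authors' enrichment, the peak at the histone gene Hist4h4 on chromosome 6 (136802801 to 136806271) ranked first at 88.98, with 72.8 and 70.4 for the overlapping peaks in the lists of replicates 1 and 2. Next came peaks nearest to Gpr146 at 85.2, Zmynd8 at 80.3, Ttll12 at 79.9, Ttc14 at 79.4, Epb41 at 79.4, Gpx1 at 78.3, Slc7a5 at 77.9, Samd14 at 77.2 and Rhoa at 76.2. In the list of replicate 2, the overlapping peaks at Gpr146 (80.4), Slc7a5 (73.5) and Ttc14 (71.3) exceeded that at Hist4h4. Epb41 encodes protein 4.1 of the red cell membrane skeleton, and Gpx1 a glutathione peroxidase.

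The gene lists were compared to ask which lists of cell type genes carry H3K27ac in this liver. The libraries were made from the tissue as a whole, so a peak cannot be assigned to a cell type. Marks of a rare cell type could also be missed. Erythroid genes were marked nearly throughout: 31 of 32 had a TSS peak, where random lists of the same size had 16.4 on average (permutation adjusted p = 0.000567). The most covered members were Hemgn, a nuclear protein of blood cell precursors, with 8955 ± 385 bp (SD, n = 2) covered within 5 kb of the TSS in the replicate lists, Slc4a1, the red cell anion exchanger, with 9752 ± 16.3 bp (SD, n = 2), and the erythroblast membrane gene Ermap with 8990 ± 28.99 bp (SD, n = 2). In the replicated list these 3 genes had 9827, 9808 and 9722 covered bp. Car1, a carbonic anhydrase, was the member without a TSS peak, while Car2 had 9219 covered bp. Of the genes picked after their values were seen, the erythroid transcription factor Klf1 had 8374 covered bp, Tal1 9588 and Gata1 2164 (9793 at another annotated TSS), and the adult globin genes Hba-a1 and Hbb-bt had 9035 and 6520. The other globin members of the list, Hba-a2, Hbb-bs, Hbb-bh1 and Hbb-y, had 8928, 7480, 5647 and 6356. Around the TSS of Hba-a1, 24.3% of 50-base words occurred elsewhere in the genome, and 35.1% around Hbb-bt.

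Heme and iron genes were covered broadly too. A TSS peak was present at 14 of 15 members, against 7.72 in random lists (permutation adjusted p = 0.00302). Replicated peaks filled the whole 10001 bp window around Fech, which encodes the last enzyme of heme synthesis, Cpox, which encodes coproporphyrinogen oxidase, and Abcb10, a transporter of the mitochondrial membrane. Their means over the replicate lists were 9898 ± 65.1, 9846 ± 219 and 9956 ± 62.9 bp (SD, n = 2). Slc25a37, which encodes the mitochondrial iron importer mitoferrin, was the member without a TSS peak, and 100% of the 50-base words around its TSS occurred elsewhere in the genome.

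Fetal hepatocyte and hepatoblast genes also had TSS peaks, at 37 of 40 members against 20.5 in random lists (permutation adjusted p = 0.000567). Apoe, an apolipoprotein, had 7722 ± 418 bp (SD, n = 2) covered in the replicate lists, the hepatoblast transcription factor Prox1 5564 ± 349 bp (SD, n = 2) and the apolipoprotein gene Apom 5352 ± 173 bp (SD, n = 2). No TSS peak was found at Fgl1, at Serpina1a, which encodes alpha-1-antitrypsin, had 43.9% of its words repeated and had a peak in the list of replicate 2, or at Ttr, which encodes transthyretin, had 962 covered bp in its wider window, with 927 and 1669 in the lists of replicates 1 and 2, and had a TSS peak in the list of replicate 2. Among genes picked after their values were seen, Alb, which encodes serum albumin, had 1555 covered bp, with 1149 and 935 in the lists of replicates 1 and 2, and a highest enrichment of 3.78, and Afp, which encodes alpha-fetoprotein, had 2687 bp and 7.46. Genes of mature hepatocyte function had TSS peaks at 5 of 25 members, against 12.8 in random lists (permutation adjusted p = 0.0051). The most covered were Aldob with 2490 ± 901 bp, Hpd with 1681 ± 154 bp and Uox with 1322 ± 81.3 bp (SD, n = 2), the other members with a TSS peak were Ass1 and Pah, and the urea cycle genes Arg1 and Cps1 had no covered base. The low count did not pass the test against random lists matched on promoter CpG, which had 5.45 members with a TSS peak (permutation adjusted p = 1), nor in the pooled-read list, where 9 of 25 had a peak (permutation adjusted p = 0.0862).

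Genes of the other blood lineages ranged from mostly marked to mostly unmarked. Megakaryocyte genes had TSS peaks at 14 of 16 members against 8.23 in random lists (permutation adjusted p = 0.00963), led by the platelet genes Gp9 with 5684 covered bp, Tubb1 with 5396 and Gp1ba with 4781, and without a TSS peak at Gp6 and Ppbp. With the peaks of replicate 2 alone the count was 13 and the test was not passed (permutation adjusted p = 0.0573). Haematopoietic stem and progenitor genes had peaks at 15 of 20 members against 10.2 (permutation adjusted p = 0.0698), with 9754 covered bp at Lmo2, 8562 at Lyl1 and 7993 at Cbfa2t3, and no TSS peak at Cd34 or Gfi1. Gfi1 had a TSS peak in the lists of replicates 1 and 2, with 525 and 311 covered bp, and Cd34 in neither. The count of this list passed the test in the pooled-read list, with 18 members (permutation adjusted p = 0.00297), in each replicate's list, and against CpG-matched lists (permutation adjusted p = 0.0462). Myeloid and macrophage genes had peaks at 10 of 21 members against 10.8 (permutation adjusted p = 0.911), with 7038 covered bp at Cd68, 2262 at Vcam1 (1427 and 1926 in the lists of replicates 1 and 2) and 1948 at Mpo, and none at Adgre1, which had one in the list of replicate 2, or C1qa. Against CpG-matched lists, which had 4.86 members with a peak, the same count was above chance (permutation adjusted p = 0.0255). The window of Cd68 also held a TSS of another protein-coding gene, so its covered bases could not be assigned to Cd68 alone. The 17 myeloid and macrophage members without such a TSS, a subset chosen after seeing the data, had a mean of 416 bp. Lymphoid genes had peaks at only 2 of 18 members, Lck and Gata3, against 9.23 (permutation adjusted p = 0.00255), with none at Bcl11b or Cd19, and Cd79a had 1825 covered bp away from its TSS, with 811 and 1447 in the lists of replicates 1 and 2. The lymphoid count was 4 in the pooled-read list and in each replicate's list, and stayed below random lists.

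The lists of other liver cell types did not pass the test on the number of members with a TSS peak. Endothelial genes had 9 of 16 (permutation adjusted p = 0.911), with 4942 covered bp at Egfl7, 3263 at Eng and 2502 at Stab1 and no TSS peak at Emcn or at Flt1, which had one in the list of replicate 1. The endothelial count was 13 in the pooled-read list, 13 in that of replicate 2 and 11 in that of replicate 1. None of these passed (permutation adjusted p = 0.0842, 0.0573 and 0.408). Stellate and mesenchymal genes had 10 of 18 (permutation adjusted p = 0.911), with 5546 covered bp at Reln, 1931 at Col1a1 and 1854 at Pdgfra (1043 and 1458, and 1831 and 849, in the lists of replicates 1 and 2) and no TSS peak at Acta2 or Col1a2. Col1a2 had a TSS peak in the lists of replicates 1 and 2, with 170 and 398 covered bp, and Acta2 in that of replicate 1, with 298. The stellate and mesenchymal count was 13 in the pooled-read list, 13 in that of replicate 1 and 10 in that of replicate 2, and did not pass. Cholangiocyte genes had 5 of 13 (permutation adjusted p = 0.639), with 6744 covered bp at the water channel gene Aqp1, 3872 at Slc4a2 and 1454 at Hnf1b (740 and 1731 in the lists of replicates 1 and 2), and no TSS peak at Cldn7 or at Cftr, where 33.1% of words were repeated and the list of replicate 2 had a peak.

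Genes of tissues outside the liver were low, and growth and housekeeping genes were high. TSS peaks were found at 1 of 20 neural genes, Gfap with 2777 covered bp (permutation adjusted p = 0.000971), at 0 of 18 cardiac and skeletal muscle genes and 0 of 15 limb and cartilage genes (permutation adjusted p = 0.000567 for both), and at 2 of 15 genes of other endoderm and kidney, Nphs1 and Lgr5 (permutation adjusted p = 0.00742). The last list no longer passed in the pooled-read list with 4 members (permutation adjusted p = 0.0584), in the list of replicate 1 with 4 (permutation adjusted p = 0.0735) or against CpG-matched lists (permutation adjusted p = 0.0515). Tubb3 had 342 covered bp (579 and 474 in the lists of replicates 1 and 2) and Dcx and Elavl3 none, Myl7 had 1466 bp and Acta1 and Actc1 none, Acan, Alx4 and Col2a1 had none, Sftpc had 386 bp (494 and 239 in the lists of replicates 1 and 2), Lgr5 976 bp, and Cdx2 and Fabp2 none, with 316 bp and a TSS peak at Fabp2 in the list of replicate 1. All 18 cell cycle genes and all 20 housekeeping genes had TSS peaks (permutation adjusted p = 0.000567 for both). Cdc6 had 9702 covered bp, Rrm2 9607 and Mcm2 7871, and Actb had 8727, Tubb5 8268 and Rpl13a 6916. In all, 12 of the 17 lists passed the test, which drew 10000 random lists for each and was two-sided; its smallest possible p of 0.0002 corresponds to the adjusted 0.000567.

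Breadth of H3K27ac around the TSS ordered the lists in another way. The median covered length within 5 kb of the TSS was 8527 bp for heme and iron genes, 6942 bp for erythroid, 4783 bp for cell cycle, 4294 bp for housekeeping, 2736 bp for fetal hepatocyte and 2732 bp for stem and progenitor genes, against 341 bp for all protein-coding genes. These 6 lists were above random lists (permutation adjusted p = 0.0051 for stem and progenitor genes and 0.00068 for the others). Stem and progenitor genes no longer passed with windows of 20 kb (permutation adjusted p = 0.0504). Medians of the other 11 lists did not pass: 828 bp for megakaryocyte, 307 bp for endothelial, 284 bp for stellate and mesenchymal, and 0 bp for the other 8 lists. Random lists often had a median of 0 bp too, so this test could not call a list lower. The window stood at the most 5' annotated TSS, which left 0 covered bp at Ank1, Hnf4a, Gata2, Erg, Rab27b, Csf1r, Gata3, Ets1, Nphs1 and Eef1a1, each with a TSS peak at another start. Other named genes had more covered bp at another start, among them Gata1 with 9793 against 2164, Gfap with 6297 against 2777, Col1a1 with 5019 against 1931 and Stab1 with 3880 against 2502. At the start with most covered bases, an alternative chosen after seeing the data, the medians were 8389 bp for erythroid, 9498 bp for heme and 3124 bp for fetal hepatocyte genes.

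**Figure D2:**
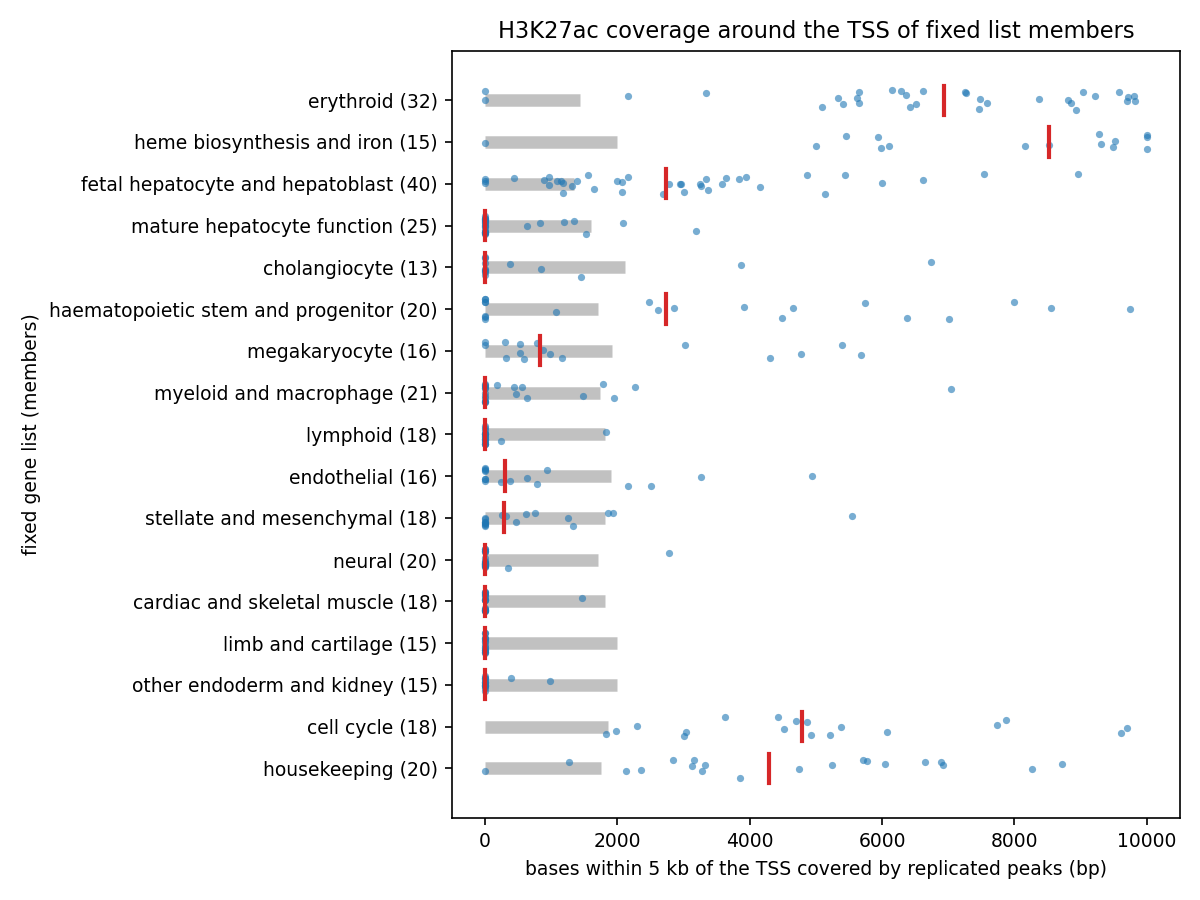
Bases within 5 kb of the TSS covered by replicated peaks (x axis, bp) for each member of the 17 fixed gene lists (y axis, members in parentheses), 1 point per gene, with the list median as a red line and the central 95% of medians of 10000 random lists as a grey bar. The medians of the erythroid, heme, fetal hepatocyte, stem and progenitor, cell cycle and housekeeping lists, 6942, 8527, 2736, 2732, 4783 and 4294 bp, lie right of their grey bars.

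List was then set against list, with genes as the units. Erythroid genes had a mean of 6735 ± 2596 covered bp (SD, n = 32) and fetal hepatocyte genes 2834 ± 2077 bp (SD, n = 40), a difference of 3902 bp (SE 564). The mean was 432 ± 829 bp for mature hepatocyte genes (SD, n = 25), 2402 bp (SE 368) below the fetal hepatocyte genes. Megakaryocyte genes had 1828 ± 2055 bp (SD, n = 16), myeloid and macrophage genes 799 ± 1605 bp (SD, n = 21) and neural genes 156 ± 622 bp (SD, n = 20). Erythroid genes exceeded these by 4907, 5936 and 6579 bp, and fetal hepatocyte genes exceeded neural genes by 2678 bp. In these 6 comparisons the two-sided permutation p was the smallest that 100000 resamples can give (permutation adjusted p = 1.33e-05). Cholangiocyte genes had 1022 ± 2038 bp (SD, n = 13), 1811 bp below fetal hepatocyte genes (permutation test, adjusted p = 0.00866), and lymphoid genes 115 ± 431 bp (SD, n = 18), 684 bp below myeloid and macrophage genes (permutation test, adjusted p = 0.049). The myeloid difference no longer passed in 4 alternatives, with permutation adjusted p of 0.0579 in the pooled-read list and 0.904 with 20 kb windows, and of 0.101 and 0.29 in 2 alternatives chosen after seeing the data, and the cholangiocyte difference no longer passed with 20 kb windows (permutation adjusted p = 0.174).

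Stitching the peaks asked which regions carry the most H3K27ac. Joining neighbouring replicated peaks gave 15377 regions, and the 1184 large ones beyond the slope-1 point of the ranked curve had at least 11144 covered bp each and held 47.5% of the covered bases. Of these, 1162 were overlapped by large regions of both replicate lists. Any overlap counted, and the replicate lists had more large regions, 1392 and 1371. Their median spans were also wider, 61696.5 and 61843 bp against 45343 bp, so this overlap is a weak check of the regions. The top region lay on chromosome 10 (79980004 to 80174751) nearest to Sbno2, with 104560 ± 1028 bp covered in the replicate lists (SD, n = 2) and 13 genes. Next were regions nearest to Hipk2, which encodes a nuclear kinase, with 114741 covered bp in the replicated list, Nol4l with 103930, Fcnb, which encodes ficolin B, with 98427, Tspan4 with 97107, Ccnd3, which encodes cyclin D3, with 96538, Lpin2 with 89790, Cpeb4 with 86319, the glucose transporter gene Slc2a1 with 85830, Nprl3 with 81542, Cd24a with 80410 and Il10rb with 80284. The region at Nprl3 on chromosome 11 (32204354 to 32320738) spanned the alpha-globin genes Hba-x, Hba-a1 and Hba-a2, with 76233 ± 571 bp covered in the replicate lists (SD, n = 2). Picked after its value was seen, the region holding the beta-globin genes, nearest to Hbb-bh2, ranked 60 with 53234 covered bp.

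**Figure D3:**
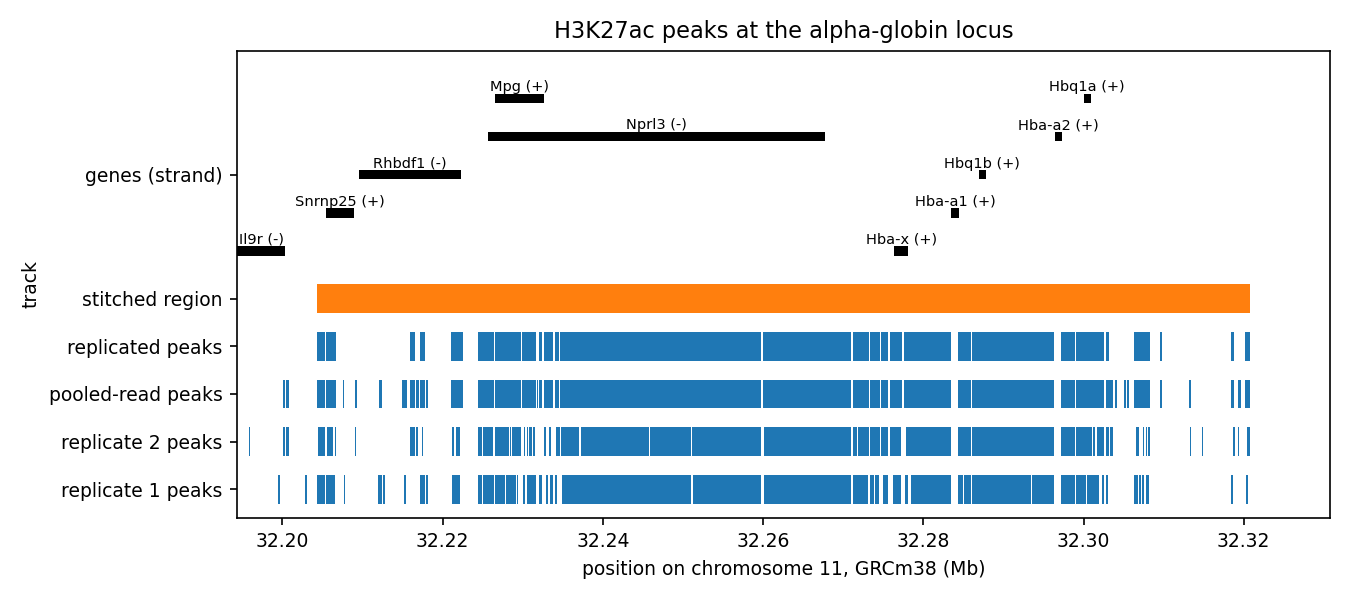
Map of the alpha-globin locus (x axis, position on chromosome 11 in Mb, GRCm38), with peaks of the 4 lists in blue, the stitched region in orange and protein-coding genes with their strand in black on tracks along the y axis. The stitched region runs from 32204354 to 32320738 and covers Nprl3, Hba-x, Hba-a1 and Hba-a2.

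Red cell genes lay in these large regions far more often than other genes. Of 32 erythroid genes, 25 overlapped a large region where 4.23 were expected (Fisher's exact test, one-sided, adjusted p = 2.19e-15), among them Klf1, Gata1, Tal1, Slc4a1, Ank1 and Bcl11a. The test treats genes as independent, but Hba-a1 and Hba-a2 share the alpha-globin region, and Hbb-bt, Hbb-bs, Hbb-bh1 and Hbb-y lie in the beta-globin region. Overlap was counted over the whole gene body, so longer genes could reach a large region more easily. For heme and iron genes the count was 13 of 15 against 1.98 (exact adjusted p = 2.53e-09). Cell cycle genes had 8 of 18 against 2.38 (exact adjusted p = 0.00667) and housekeeping genes 8 of 20 against 2.64 (exact adjusted p = 0.0113), or 14 and 12 in the lists of replicates 1 and 2. Stem and progenitor genes had 7 of 20, namely Runx1, Lmo2, Spi1, Ikzf1, Lyl1, Ldb1 and Cbfa2t3 (exact adjusted p = 0.0384), a call that was not passed with the list of either replicate alone (exact adjusted p = 0.175 and 0.0585) or with stitching at 25 kb (exact adjusted p = 0.17). Fetal hepatocyte genes had 6 of 40 against 5.29 (exact adjusted p = 0.931), at Apoa2, Apoe, Apom, Hnf4a, Foxa3 and Dlk1, or 10 and 11 in the lists of replicates 1 and 2, which did not pass either. The other lists had 5 of 16 megakaryocyte, 3 of 16 endothelial, 2 of 21 myeloid and macrophage (4 and 5 in the lists of replicates 1 and 2), 2 of 13 cholangiocyte, 1 of 25 mature hepatocyte, 1 of 18 lymphoid (2 in the list of each replicate) and 1 of 15 other endoderm and kidney genes, and 0 in the stellate, neural, muscle and limb lists, none past the test. With the list of either replicate alone, 1 stellate and 1 neural gene overlapped a large region, also not past the test.

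Binding words of transcription factors were counted in the 31688 peaks more than 2.5 kb from a TSS. The E-box-GATA composite, the word bound by the TAL1 and GATA1 complex, was 2.09 times as dense in these peaks as in windows 10 kb away, with 1870 matches against 973. The NFE2 word was 2.80 times as dense (365 matches against 141), the shorter AP1/NFE2 core 1.30 times (5877 against 4901) and the HNF1 word of hepatocyte promoters 1.61 times (24 against 16). Each of these 4 ratios exceeded those of all 100 letter-shuffled versions of the word (permutation p = 0.0198, adjusted p = 0.0792). The unadjusted p was the smallest this test could give. Only these 4 of the 16 words reached it, too few for an adjusted p under 0.05, so 0 words passed the threshold. With 1000 shuffled versions that share no word with the consensus, chosen after seeing the data, the same 4 words passed (permutation adjusted p = 0.0107 for the first 3 and 0.016 for HNF1). The HNF1 ratio rests on few matches and was 0.792 and 0.716 in the peaks of replicate 2 and replicate 1 alone. The plain GATA word was less dense in peaks than beside them, at 0.934 times, and 95 of its 100 shuffled versions were lower still. FOXA had a ratio of 1.10, HNF4 1.21, CEBP 1.31 with 35 matches against 29 and 0.845 in the peaks of replicate 2 alone, KLF 1.33, RUNX 1.01, ETS 0.996 with 77 matches and above 1 in the peaks of either replicate alone, and CTCF 0.330 with 3 matches, and among words not chosen for liver MEF2 had 1.09, SOX 1.06, homeobox 0.702 and NRSF 1 match against 0. Out of 100 shuffled versions each, FOXA exceeded 99, CEBP 93, RUNX 90, HNF4 86, KLF 79, ETS 34 and CTCF 6. Among words not chosen for liver, MEF2 exceeded 98, NRSF 94, homeobox 84 and SOX 66, so MEF2 came close to FOXA.

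**Figure D4:**
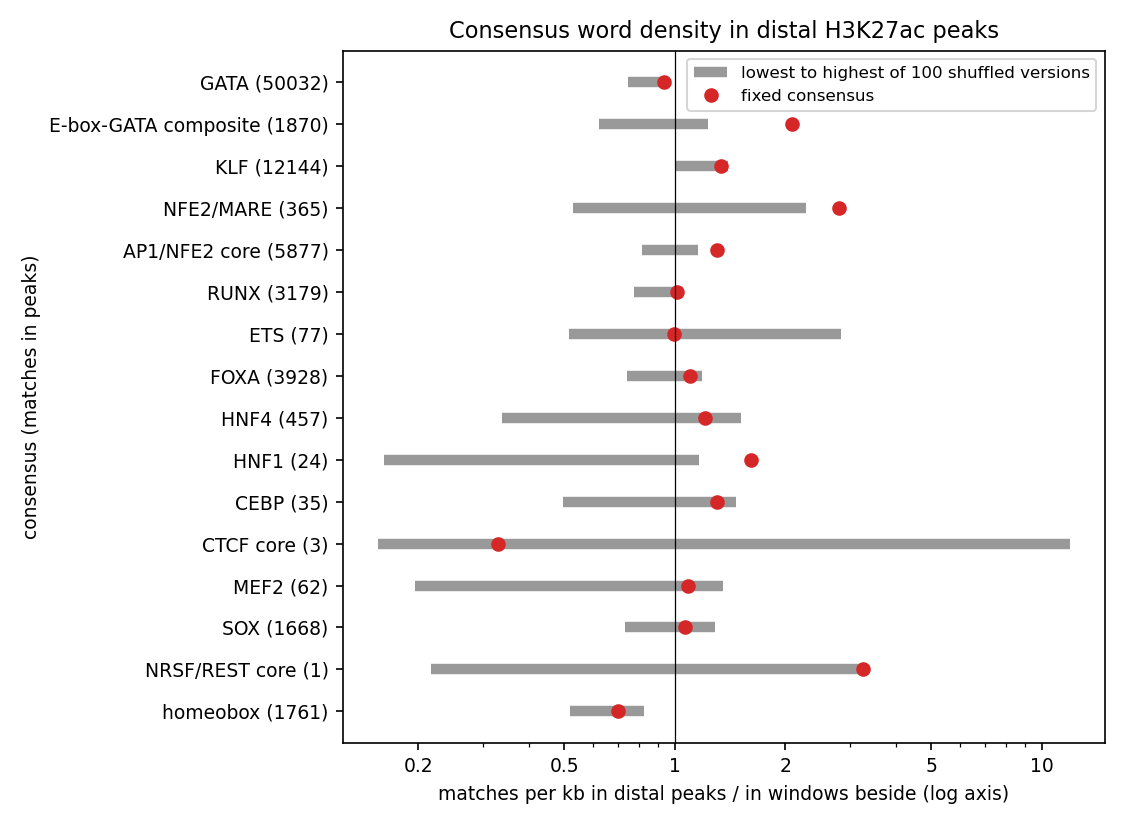
Matches per kb in distal peaks over matches per kb in windows beside them (x axis, log scale) for the 16 fixed words (y axis, matches in peaks in parentheses), with the word as a red point and the lowest to highest of 100 shuffled versions as a grey bar. E-box-GATA at 2.09, NFE2/MARE at 2.80, AP1/NFE2 core at 1.30 and HNF1 at 1.61 lie right of their grey bars.

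Along the genome, the X chromosome had fewer covered bases per Mb than any autosome. Autosomes had between 15048 bp per Mb on chromosome 14 and 44351 bp per Mb on chromosome 11, with a median of 23884. The X chromosome had 5182 bp per Mb, and 4768 and 5134 bp per Mb in the lists of replicates 1 and 2. On the X, 291 of 948 genes (30.7%, Wilson 95% interval 27.8 to 33.7) had a TSS peak, against 10944 of 20780 autosomal genes (52.7%). Alas2, the erythroid enzyme that starts heme synthesis, was among the X genes with a peak, with 5942 covered bp, as were Gata1 with 2164 at its most 5' TSS and 9793 at another, and Hprt with 2354. The Y chromosome had 2 peaks in each list.

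**Figure D5:**
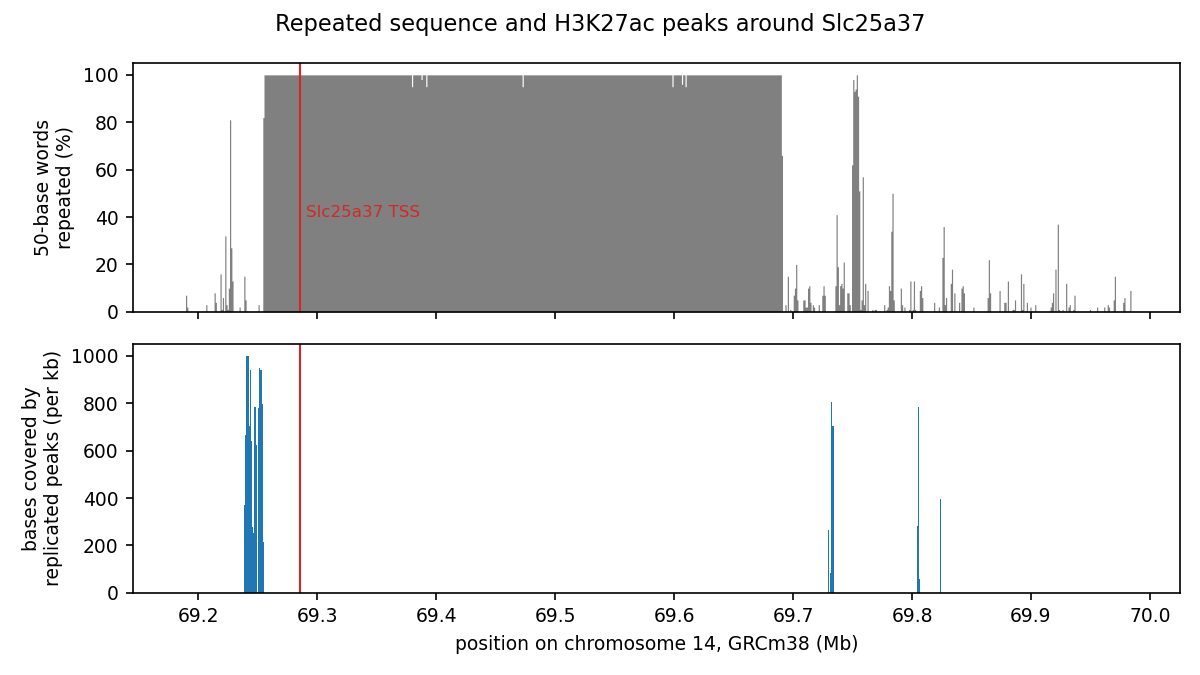
Percentage of 50-base words that occur elsewhere in the genome (upper panel, y axis) and bases covered by replicated peaks (lower panel, y axis, bp) in 1 kb bins along chromosome 14 (x axis, Mb, GRCm38), with the TSS of Slc25a37 as a red line. The TSS lies in a block of 435 kb with at least 90% of words repeated and 0 peaks.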

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

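Apart from the CpG-matched random lists, the tests in this part were chosen only after the pattern they weigh was seen. That holds for genes with under 10% of words repeated and for members without another gene in the window. The X genes were compared on CpG content and repeated words together only after both single tests were seen.

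Outside the assembled chromosomes the replicated list had 6 peaks. They are flagged as peaks on sequences left out of every comparison with genes, and no number of peaks was expected on them. The widest spanned 1950 bp with an enrichment of 45.0.

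Slc25a37 and 20 of 25 mature hepatocyte genes had no TSS peak. For Slc25a37, unknown bases are argued against, since they made up 0% of the 10 kb around its TSS, while reads shared with a near-identical copy may account for the missing peak: 100% of the 50-base words there occur again, in a block of 435 kb with 0 peaks in all 4 lists. For mature hepatocyte genes shared reads are argued against, with at least 50% of words repeated at 2 of the 20 genes. Low promoter CpG content could account for the count, since 24 of the 25 members lie in the lowest 2 quintiles. CpG-matched random lists had 5.45 members with a TSS peak (range of the central 95%, 2 to 10), against 5 observed and 12.8 in unmatched lists (permutation adjusted p = 1 after matching). Low CpG content did not leave the fetal hepatocyte and erythroid lists unmarked, though. In these quintiles lie 29 of 40 fetal hepatocyte and 21 of 32 erythroid members, yet 37 and 31 members of these lists had a TSS peak. The matching thus shows a count usual for genes of such CpG content, not that CpG content is its cause. No biological explanation was tested, as the design has 1 group.

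X-linked genes had a TSS peak less often than autosomal genes, 30.7% against 52.7%. CpG content alone is argued against, since autosomal genes of the same CpG quintiles would give 43.4%, above the upper bound of 33.7%, and so are shared reads alone, since a gap of 15.8 percentage points stayed among genes with under 10% of words repeated, against 22.0 before. With both at once, 51.1% of such X genes would have a peak against 42.5% observed, so together they could account for part of the gap. Fewer active copies per cell remain a candidate explanation: at X genes with a TSS peak in the upper 2 CpG quintiles the median of the authors' top enrichment was 0.729 times that of autosomal genes, 10.1 against a central 95% of 11.6 to 16.6 for autosomal sets of the same size (131 genes). This ratio holds the X dose of male embryos and the inactive X of female embryos together, which could not be separated in pooled tissue. It could not single out copy number either, since any cause of weaker signal at X genes would lower it. Genes with repeated words were not left out of this test.

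Erythroid genes had 3902 bp more covered than fetal hepatocyte genes. Promoter CpG content is argued against, with a difference of 3959 bp within CpG quintiles, as are other genes inside the window, with 4291 bp between 25 and 32 members without one, and shared reads, with 3892 bp between 27 and 39 members with under 10% of words repeated. In each the permutation p was the smallest that 100000 resamples can give. The share of erythroid cells in the tissue stays open and untested, since no cell counts are given in the sources used here, and the design gives no biological group to test.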

How the results depend on the processing

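The tests chosen only after the result was seen are those with the 20000 top peaks, strict against all peaks, under 10% of words repeated, the most covered TSS, members alone in the window, and 1000 shuffled versions sharing no word with the consensus. The depth of the libraries is unknown, so what it limits was not measured, and the causes of the changes below were not tested unless stated. Of 108 alternatives for list genes near stitched regions 105 kept their side of the threshold and, where past it, their direction, as did 161 of 162 for list coverage, 133 of 144 for list TSS peaks, 67 of 72 for list pairs and 114 of 119 for words. Each total also holds, for each setting, the number of lists, pairs or words that passed. That number has no side of a threshold and counted as kept when equal or within 1.5 times. For words, 1 of the changes was in that number. Lists and words not past the threshold changed direction in some of these alternatives. Covered bases of named genes, judged by another rule, stayed the same or within the SD of the replicates in 250 of 432 alternatives and moved further in 182, among them windows of other sizes, which change the count by construction. Large regions and genes with a TSS peak stayed within 1.5 times in each of 7 and 6 alternatives.

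With a -log10 q of at least 2 the replicate lists held a mean of 83366 peaks, overlap was 54.0%, rank correlation 0.684, and 68.0% of replicated peaks were overlapped by both lists. With overlap by 1 base these were 56.9%, 0.637 and 82.2%, with 50% of both peaks 32.7% and 49.9% for the first and last. Equal numbers of top peaks gave 51.1%, the 20000 top peaks 83.5% and strict against all peaks 58.2%. The share of peaks at a TSS was 26.0% in the pooled-read list, 27.6% to 27.8% without 1 replicate, and by construction 30.4% and 47.5% with windows of 500 bases and 2.5 kb.

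Members with a TSS peak in the pooled-read list were 9 for mature hepatocyte, 18 for stem and progenitor and 4 for other endoderm and kidney genes. Without 1 replicate they were 16 to 17 for stem and progenitor, 13 to 14 for megakaryocyte and 3 to 4 for other endoderm and kidney genes. Against CpG-matched lists the counts of 5 mature hepatocyte (permutation adjusted p = 1) and 2 other endoderm and kidney genes no longer passed, the 15 stem and progenitor genes passed, and the 10 myeloid genes went from just below to above chance (permutation adjusted p = 0.0255).

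Stem and progenitor coverage in 20 kb windows was 3867 bp and no longer passed. Myeloid minus lymphoid no longer passed at 752 bp in the pooled-read list, 162 bp in 20 kb windows, 696 bp at the most covered TSS and 276 bp for members alone in the window, nor did fetal hepatocyte minus cholangiocyte at 2291 bp in 20 kb windows. Stem and progenitor genes near large regions no longer passed, with 7 to 8 without 1 replicate and 7 at 25 kb. With 1000 shuffled versions sharing no word with the consensus, which changed the number of versions and their choice together, 4 words passed instead of 0, at 2.09, 2.80, 1.30 and 1.61.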

Other observations

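The values in this part were chosen only after they were seen. Some of the widest H3K27ac regions held no protein-coding gene: 56 of the 1184 large regions (4.73%). The top one, nearest to the proto-oncogene Myc, lay 112954 bp from its TSS on chromosome 15 (62098345 to 62241431), ranked 19 among all regions and had 62548 ± 3502 bp covered in the replicate lists (SD, n = 2). Others of this kind were nearest to Picalm, with 53335 covered bp at rank 59, Podxl with 42866 bp, and Hbs1l with 25031 bp, 21878 bp from its TSS. Hbs1l is the neighbour of Myb, a transcription factor of blood progenitors.

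Some large regions overlapped a single protein-coding gene, and could extend beyond it. They included those at the kinase gene Bmp2k with 79895 covered bp, Prkar2b with 79748 and Pim1 with 65519. Others lay at the hepatic lipase gene Lipc with 63178, Smad6 with 62760, and the erythroid list member Bcl11a with 58205. A region at rank 15 nearest to Hist1h3e overlapped 16 protein-coding genes at a histone gene cluster on chromosome 13, with 77451 covered bp and 70840 ± 523 bp in the replicate lists (SD, n = 2).

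Genes with mostly repeated sequence around the TSS rarely had a peak. Of 1194 protein-coding genes with at least 50% of words repeated, 23 (1.93%) had a TSS peak, against 52.4% of the 4296 genes with under 1% repeated. Between these, the share was 59.4% of 13952 genes with 1% to 10% repeated and 27.6% of 2469 genes with 10% to 50%. Whether the genes with most repeated words are inactive in this tissue was not tested.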
